A study of Mus musculus with 7 samples.

How the data were processed

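Open chromatin was measured by ATAC-seq in 7 libraries of sorted mouse pancreatic acinar cells, 3 with wild-type p53 (p53 WT) and 4 with floxed Trp53 (p53 KO), each made from 50000 cells per the labels' protocols. The titles call the libraries biological replicates, and groups and replicate numbers were taken from those titles. The WT mice were about 3 months old and the KO mice about 1 month old, so age was carried by the same contrast as genotype and was not a covariate. Bowtie, Picard, MACS2 and DESeq2 and the mm10 build are named per the submitters' processing notes, while their versions, their order and their parameters are not given in the sources used here.

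The authors deposited, for each library, a list of fragments with start, end and strand. The deposited fragments lay on the 19 autosomes and were between 22 and 1992 bp long. Whether the fragment ends had been moved for the Tn5 offset is not given in the sources used here. The authors deposited a peak list for each library, and each peak in these lists carries a fold enrichment (a ratio), a −log10 p and −log10 q of the peak caller and a normalised score between 0 and 1, per the file headers. These are the authors' own values for each peak and were used only to rank peaks within a library. The authors also deposited 161620 consensus peaks of equal width, whose construction is not given in the sources used here.

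The authors' deposited table compares KO with WT at every consensus peak, and its column names are those of a DESeq2 result, per the file headers. The authors' deposited table gives a log2 fold change with its standard error, a p-value and an adjusted p-value for each peak. It also gives a deposited mean signal, which is the mean over libraries of counts divided by size factors. The same deposited table gives group means on a variance-stabilised scale close to log2, and group means of log10 FPKM. The design formula behind the authors' test is not given in the sources used here, and no per-library count was taken from that table.

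Fragments were counted again from the deposited fragment positions, because the files used here held no count per peak and library. A fragment counted once in a consensus peak when at least 1 of its 2 ends lay inside. Counts were scaled by the median of ratios, peaks with a mean count under 10 over the 7 libraries were left out, and 148420 peaks were tested. The test was limma-voom with genotype as the only term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. limma-trend on log2 CPM with a pseudocount of 1 was the second tool. Exact permutation tests of a single value used all 35 splits of the libraries into 3 and 4, and the smallest two-sided p such a test can give is 0.0571. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, R 4.3.3 with limma 3.58.1, and bedtools 2.31.1 were used.

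Peaks were placed against protein-coding genes of the RefSeq annotation of GRCm38.p6, the assembly that mm10 names. The gene table used here has no strand, so the start and the end of transcription could not be told apart by position. A gene-end peak therefore lies within 1 kb of either end of a protein-coding gene and stands in for a promoter peak. A peak was assigned to the nearest gene end within 2 kb, otherwise to the gene that contains it, otherwise to the nearest gene end within 100 kb, and 8787 tested peaks had no gene. Positions are 1-based mm10 coordinates.

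Gene groups comprised 18 lists with 469 entries. Those reported here were p53 target genes, acinar digestive enzymes and secretory products, acinar transcription factors, ductal and progenitor genes, gastric-type metaplasia and neoplasia genes, cell cycle genes, epithelial-mesenchymal transition genes, Hippo-YAP target genes, inflammation and acute-phase genes, interferon response genes, unfolded protein response genes, and constitutive reference genes. Markers of other cells formed the remaining lists, for immune, fibroblast and stellate, endothelial, endocrine and erythroid cells. Each list was tested with limma's camera over the peaks assigned to its genes, with a preset correlation of 0.01 between peaks and again with an estimated correlation, adjusted over the 18 lists. A list mean is the mean log2 accessibility of its peaks in a library minus the mean over all tested peaks of that library.

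The lists, the tests, 36 alternatives and the rule for named genes were fixed before the data were examined. The rule always names Trp53, Ptf1a, Cdkn1a and Mdm2, each by its strongest gene-end peak and its peak of smallest p. It then names, in each direction, up to 6 gene-end and 6 distal peaks past the threshold whose KO libraries all lie on one side of all WT libraries, largest change first, 1 per gene and without symbols of the Gm or Rik kind. From each list it names up to 2 genes per direction with called peaks, or, without a call, the gene whose peak has the smallest p. Other genes named below were chosen after their values were seen. Some items of the genotype, the lists and the rule, 1 list among them, are not reported here.

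Fragment ends outside peaks were counted in bins of 100 kb, leaving out 250 bp on each side of every consensus peak. Bins with a mean of at least 50 ends and at least 50% of their length outside peaks were fitted with limma-voom in the same way. The fitting code was tested on simulated counts with 200 changed peaks among 148420. It recovered 2% of peaks changed 2-fold, 18% of those changed 4-fold, 58% of those changed 8-fold and 98% of those changed 32-fold, and called 3 unchanged peaks. The libraries held between 17259873 and 35036982 fragments, the tested peaks had a median mean count of 24.4, and the median standard error of a log2 fold change was 0.41.

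Alternatives covered the scaling, the count filter, what is counted, a replicate block, the share of fragments in peaks as a covariate, the tool, thinning to the shallowest library and leaving out each library. Motif content and GC corrections were not run because no genome sequence was used here. Chromosomes X and Y, and so the sex of the mice, were not analysed here.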

Results

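Chromatin accessibility was profiled by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in acinar cells of the mouse pancreas. Acinar cells make and secrete the digestive enzymes. All mice carried Ptf1a-Cre, a recombinase that acts in the pancreas. Their Trp53 gene, which encodes the tumour suppressor p53, was either wild type (3 libraries, p53 WT) or floxed on both chromosomes, a form this Cre can delete (4 libraries, p53 KO). Cells were sorted for CD49F and against CD133, TER-119 and CD45, markers of ductal-like, erythroid and immune cells. The WT mice were about 3 months old and the KO mice about 1 month old, so each difference between genotypes was also a difference in age. The WT libraries held 22832257, 35036982 and 21851984 fragments and the KO libraries 18435918, 17259873, 23909141 and 25443848. The comparison asks how loss of p53 alters open chromatin in these acinar cells.

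The targeted gene was examined first. Fragment ends in the Trp53 gene body outside consensus peaks were fewer in every KO library than in every WT library, at 52.0% of the WT level. Relative to 1000 ends outside peaks in the flanking 100 kb on each side, the gene body held 54.7 ± 9.11 ends (SD, n = 3) in WT and 28.4 ± 7.23 (SD, n = 4) in KO. The KO libraries ranged from 18.7 to 36.1 and the WT libraries from 45.2 to 63.3, and the exact two-sided permutation p was 0.0571, the smallest this design can give. Trp53 spans chromosome 11 from 69580348 to 69591873, and this measure was chosen after the data were seen. With the ends inside the peak counted too, the values were 50.2 ± 10.1 (SD, n = 3) in WT and 40.2 ± 7.55 (SD, n = 4) in KO, with an exact permutation p of 0.229. The 1 consensus peak of Trp53 (69581279 to 69581779) lay within the gene, 931 bp from its boundary of lower coordinate. It had 141 ± 6.84 normalised fragments (SD, n = 3) in WT and 138 ± 33.6 (SD, n = 4) in KO. Its limma-voom log2 fold change was −0.04 (adjusted p = 0.983). The borders of the deleted interval are not given in the sources used here, so how complete the deletion was in the sorted cells could not be told from these values.

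**Figure D1:**
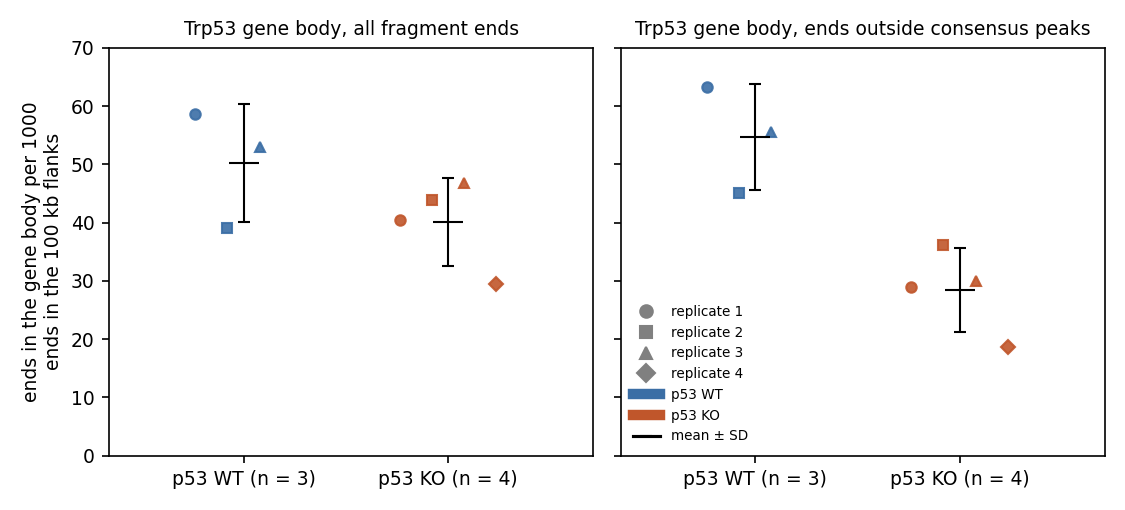
Fragment ends in the Trp53 gene body per 1000 ends in the flanking 100 kb, for each library, over all ends (left) and over ends outside consensus peaks (right), with bars for the mean ± SD of each genotype. Outside peaks the 4 KO libraries lie between 18.7 and 36.1, all below the 3 WT libraries, which lie between 45.2 and 63.3.

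The share of fragments in consensus peaks was 40.9%, 28.9% and 47.3% in the WT libraries and 41.6%, 35.2%, 38.6% and 28.5% in the KO libraries (exact permutation p = 0.629). Enrichment of fragment ends at gene ends was 17.1 ± 2.21 (SD, n = 3) in WT and 14 ± 2.08 (SD, n = 4) in KO (exact permutation p = 0.171). The exact permutation p was 0.343 for fragments per library and 0.8 for the share of fragments under 150 bp, and the adjusted p over these 4 measures was at least 0.686. WT libraries resembled each other less, with a mean Spearman correlation across peaks of 0.638, than KO libraries did, at 0.777, and the mean between genotypes was 0.710. The first principal component held 60.6% of the variance and ran through both genotypes, from WT 1 at −122 to KO 4 at 89.7, with WT 3 at 76.1 (exact permutation p = 0.343). The third component held 10.5% of the variance and placed all WT libraries above all KO libraries (exact permutation p = 0.0571).

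**Figure D2:**
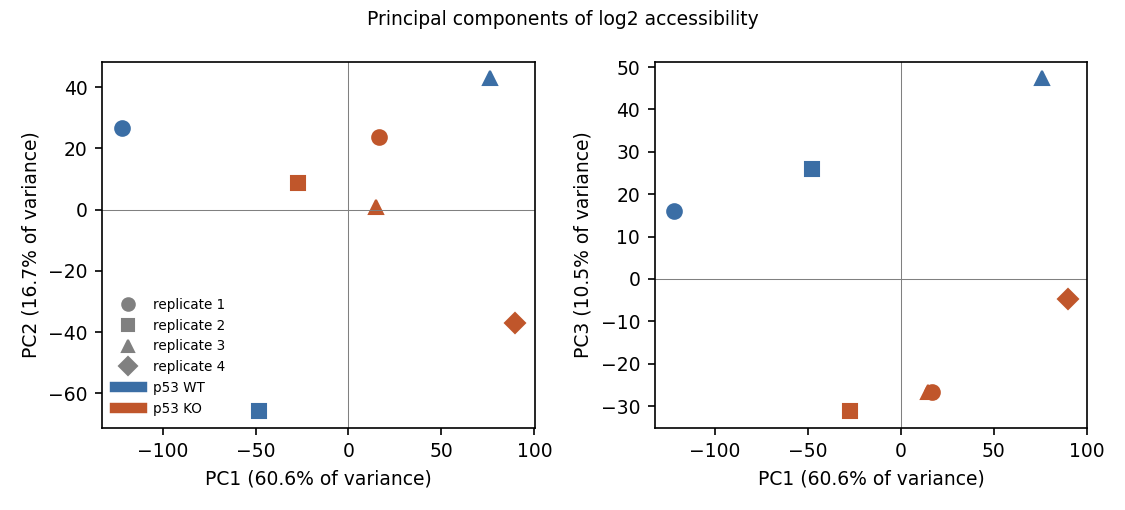
Principal components of log2 accessibility over 34313 consensus peaks, one point per library, with the first against the second component (left) and the first against the third (right). WT libraries spread along the first component, which holds 60.6% of the variance, and the third component, with 10.5%, separates the genotypes.

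At single peaks the genotypes differed at 4 sites, all of them strongly reduced in KO and all in 1 region of chromosome 12. The gene-end peak of LOC108167368, a predicted gene (20614709 to 20615209), had 190 ± 55.9 normalised fragments (SD, n = 3) in WT and 1.92 ± 1.09 (SD, n = 4) in KO. A peak nearest to LOC115488029, also a predicted gene (19288249 to 19288749), had 50.3 ± 11.6 (SD, n = 3) in WT and 0.322 ± 0.645 (SD, n = 4) in KO. A peak with no gene within 100 kb (20990207 to 20990707) had 177 ± 24.5 (SD, n = 3) against 22 ± 7.03 (SD, n = 4), and a peak nearest to Gm46305 (21784305 to 21784805) had 87.1 ± 27.2 (SD, n = 3) against 1.06 ± 1.46 (SD, n = 4). The last pair falls outside the rule for named genes and was named after its values were seen.

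These 4 of 148420 tested peaks passed limma-voom with Benjamini-Hochberg adjustment, all lower in KO, with adjusted p of 0.0147 for LOC108167368 and LOC115488029, 0.0189 for the peak without a gene and 0.0245 for Gm46305. Summed fragments were divided by the summed scaling factors of the libraries of each genotype. The ratio of WT to KO was then 103 (95% interval 49.7 to 257) at LOC108167368, from 627 against 7 unscaled fragments. It was 192 (34 to 7625) at LOC115488029, from 167 against 1, and 83.3 (32.2 to 308) at Gm46305, from 290 against 4. At the peak without a gene it was 8.28 (6.56 to 10.6), from 584 against 81. These exact intervals cover counting error alone. No peak passed in the other direction, where 3768 peaks had an unadjusted p under 0.05 and the smallest adjusted p was 0.285, and limma-trend called 9 peaks in all. In total 7734 peaks (5.21%) had an unadjusted p under 0.05, and KO lay entirely on one side of WT at 5.71% of peaks, where chance gives 5.71%. With 1 library left out at a time the fitted log2 fold changes of these peaks stayed near their size, from −6.62 to −6.09 at LOC108167368 (SE up to 0.74), from −6.64 to −5.92 at LOC115488029 (SE up to 0.71), from −3.21 to −2.85 at the peak without a gene (SE up to 0.36) and from −6.78 to −5.75 at Gm46305 (SE up to 0.80). Their highest unadjusted p was 1.1e-05. With fewer libraries the adjusted p often rose above 0.05, and 0 peaks were called without KO 1, KO 3 or KO 4 and 1, among the same 4, without KO 2. Without WT 1 the count was 2, of which 1 was among the 4, without WT 2 it was 3, of which 0 were, and without WT 3 it was 7, including all 4. Fragment ends outside peaks in the same 100 kb bins were lower too, with log2 fold changes of −2.62 around LOC115488029, −0.59 around LOC108167368, −0.44 around the peak without a gene and −2.66 around Gm46305.

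**Figure D3:**
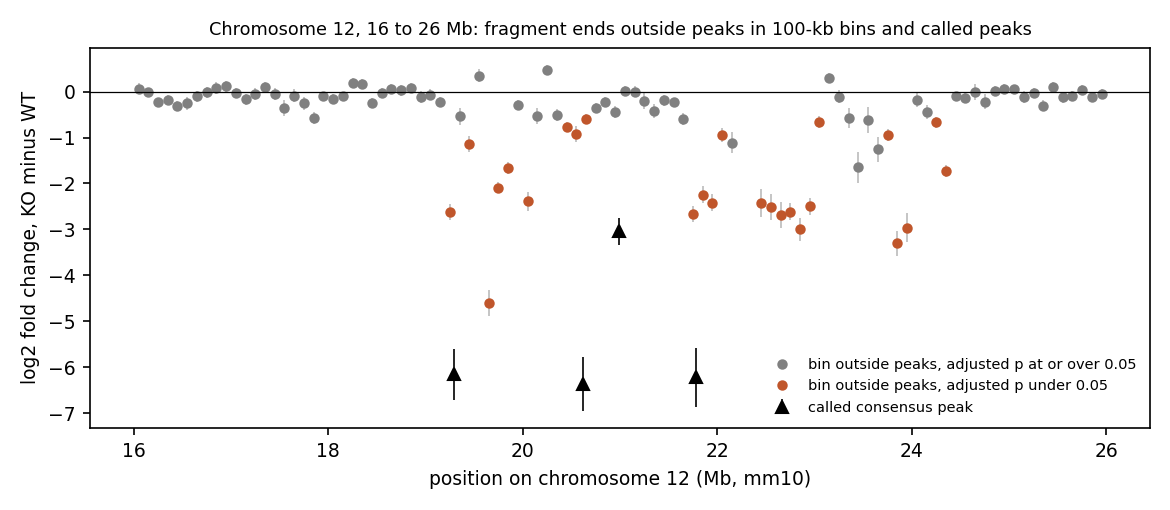
Log2 fold change of KO over WT (vertical axis) along chromosome 12 from 16 to 26 Mb in mm10 (horizontal axis), for fragment ends outside peaks in bins of 100 kb (circles) and for the 4 called peaks (triangles), with bars for the standard error. Of the 98 bins, 25 had an adjusted p under 0.05, all lower in KO.

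The genes followed in every case had no peak past the threshold. Mdm2, which encodes the ubiquitin ligase that degrades p53 and is itself a p53 target, had its strongest gene-end peak on chromosome 10 (117710581 to 117711081), at 463 ± 70.9 normalised fragments (SD, n = 3) in WT and 352 ± 19.4 (SD, n = 4) in KO. All KO libraries lay below all WT libraries there (log2 fold change −0.38, SE 0.17, limma-voom adjusted p = 0.876). Cdkn1a, which encodes the cell cycle inhibitor p21 and is a p53 target, had a weak gene-end peak on chromosome 17 (29100721 to 29101221). It held 10.99 ± 4.81 normalised fragments (SD, n = 3) in WT and 16.4 ± 5.02 (SD, n = 4) in KO. The log2 fold change was 0.60 (SE 0.43) there and 1.09 (SE 0.51) at a peak 3200 bp away. This gene-end peak lies at the boundary of Cdkn1a with the higher coordinate. Whether that is the start or the end of transcription could not be told without strand, so accessibility at its promoter stays undecided. Ptf1a, a transcription factor of acinar cells, had 195 ± 264 fragments (SD, n = 3) at its gene-end peak on chromosome 2 (19445261 to 19445761) in WT and 286 ± 113 (SD, n = 4) in KO. Its WT libraries stood at 56.0, 30.5 and 499.9 (log2 fold change 1.54, SE 0.68, adjusted p = 0.876).

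Chromatin around the genes of digestive enzymes was more open in all 4 KO libraries than in 2 of the 3 WT libraries. The mean log2 accessibility of the acinar enzyme list, relative to all peaks, was −0.30 ± 0.23 (SD, n = 4) in KO and −1.13 ± 0.86 (SD, n = 3) in WT. The WT libraries were far apart, with WT 1 at −1.77, WT 2 at −1.47 and WT 3 at −0.15, the last within the range of the KO libraries from −0.63 to −0.07. Of 304 peaks around 36 enzyme genes, 98 had an unadjusted p under 0.05 and a higher value in KO, around 25 genes, and 0 a lower one. Examples chosen after their values were seen were the gene-end peaks of Try5 and Prss2, which encode trypsinogens, with log2 fold changes of 1.97 (SE 0.59) and 1.67 (SE 0.53), Ctrb1, for chymotrypsinogen, with 1.72 (SE 0.64), and Cpa1, for a carboxypeptidase, with 1.33 (SE 0.51). Try4 held the peak of smallest p, with a log2 fold change of 2.02 (SE 0.55).

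The acinar enzyme list passed camera with the preset correlation (adjusted p = 2.5e-33), and with an estimated correlation its adjusted p was 0.874. The difference of list means was 0.84, with an exact permutation p of 0.229. Limma's fry, which tests the list's own fold changes against 0 and not against other peaks, gave an adjusted p of 0.893. The difference of list means was 0.52 without WT 1 and 1.33 without WT 3. With only WT 3 kept, a setting chosen after the data were seen, this difference was −0.13. Over the list alone, and over all peaks, 0 of its peaks were called by limma-voom and 0 by limma-trend.

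Other lists higher in KO were those of acinar transcription factors, the unfolded protein response and constitutive reference genes. The acinar transcription factor list was higher in KO by 0.32 (camera adjusted p = 8.7e-08, and adjusted p = 0.874 with an estimated correlation), with values of −0.81, −0.49 and 0.10 in WT and from −0.30 to 0.11 in KO. The difference was 0.11 without WT 1 (adjusted p = 0.0400), 0.56 without WT 3 (adjusted p = 1.2e-10) and −0.18 with only WT 3 kept. Of its 392 peaks, 28 were higher and 2 lower at an unadjusted p under 0.05, and Mecom, a zinc finger factor, held the smallest p with a log2 fold change of 0.98 (SE 0.32). The unfolded protein response list, genes that adjust protein folding in the endoplasmic reticulum, was higher in KO by 0.29 (camera adjusted p = 5.5e-05, and adjusted p = 0.874 with an estimated correlation). The call ended without WT 1 (0.08, adjusted p = 0.427), without the pair of libraries of lowest share in peaks (0.16, adjusted p = 0.0601) and among gene-end peaks alone (0.13, adjusted p = 0.335), and the difference was 0.59 without WT 3 (adjusted p = 8.4e-10). With only WT 3 kept the list difference was −0.29. Its peak of smallest p lay 4442 bp from Dnajc3, with a log2 fold change of 1.88 (SE 0.50), while the strongest gene-end peaks of Sel1l and Manf, named after their values were seen, were at −0.41 (SE 0.12) and −0.44 (SE 0.14). The constitutive reference list was higher in KO by 0.15 (camera adjusted p = 0.0233, and adjusted p = 0.874 with an estimated correlation). This call ended without WT 1 (0.04, adjusted p = 0.579), without KO 3 (0.13, adjusted p = 0.0968) and among gene-end peaks alone (0.07, adjusted p = 0.499), and the difference was 0.25 without WT 3 (adjusted p = 0.00699).

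Markers of fibroblasts and stellate cells, for which the sort used no excluding marker beside its selection for CD49F, were lower in KO by 0.25 (camera adjusted p = 0.00672, and adjusted p = 0.874 with an estimated correlation). The list mean was −0.27 ± 0.69 (SD, n = 3) in WT and −0.51 ± 0.30 (SD, n = 4) in KO. Its peak of smallest p, near Pdgfrb, had a log2 fold change of 0.95 (SE 0.30), against the direction of the list. The call ended without WT 1 (0.07, adjusted p = 0.467), without WT 2 (−0.17, adjusted p = 0.246) and without KO 4 (−0.11, adjusted p = 0.283). It also ended with a replicate block (−0.11, adjusted p = 0.159) and without the pair of libraries of lowest share in peaks (−0.04, adjusted p = 0.891). The difference was −0.62 without WT 3 (adjusted p = 2.9e-10) and 0.52 with only WT 3 kept. Markers of immune cells differed by −0.13 (camera adjusted p = 0.176), of endothelial cells by 0.06 (0.237), of endocrine cells by 0.01 (0.934) and of erythroid cells by 0.09 (0.585). The immune list was called lower without WT 3 (−0.31, adjusted p = 0.00699), with quantile normalisation (−0.17, adjusted p = 0.0476) and with the share in peaks as a covariate (−0.19, adjusted p = 0.0453). The endothelial list was called higher without WT 1 (0.17, adjusted p = 0.00892), without KO 1 (0.11, adjusted p = 0.0393) and without KO 4 (0.12, adjusted p = 0.0385), as it was with a replicate block (0.12, adjusted p = 0.0215) and without the pair of libraries of lowest share in peaks (0.18, adjusted p = 0.00704). Its difference turned to −0.10 without WT 3 (adjusted p = 0.372) and −0.04 without KO 2 (adjusted p = 0.895). These immune and endothelial calls used the preset correlation of 0.01, and no estimated correlation was fitted in these settings. Over all libraries it was estimated at 0.093 for the immune and 0.178 for the endothelial list, and each then had a camera adjusted p of 0.874. With only 1 WT library kept, a setting without replicates of WT, the endothelial difference was 0.39 with WT 3 and the immune difference −0.38 with WT 2. The peaks of smallest p in the immune, endothelial and endocrine lists lay near Cd3g, Erg and Pcsk2, with log2 fold changes of 1.78, −1.63 and −1.15. At an unadjusted p under 0.05 the immune, endothelial, endocrine and erythroid lists held 1, 5, 0 and 0 peaks higher and 1, 3, 3 and 0 lower in KO, and none was called by limma-voom or limma-trend.

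**Figure D4:**
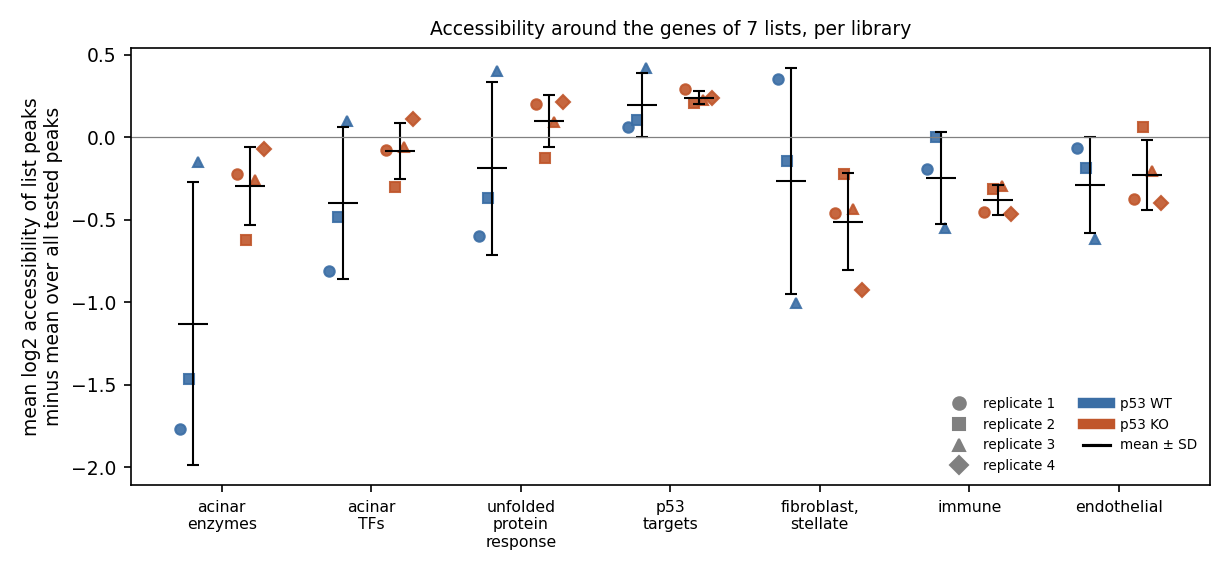
Mean log2 accessibility of the peaks of 7 gene lists minus the mean over all tested peaks (vertical axis), one point per library, with bars for the mean ± SD of each genotype. In the acinar enzyme list WT 1 and WT 2 lie at −1.77 and −1.47, while WT 3, at −0.15, lies within the KO range of −0.63 to −0.07.

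For the p53 target genes as a group no difference between genotypes was detected. Their list mean was 0.19 ± 0.19 (SD, n = 3) in WT and 0.24 ± 0.04 (SD, n = 4) in KO, and camera gave an adjusted p of 0.623. Of 388 peaks around 37 target genes, 18 were higher and 16 lower in KO at an unadjusted p under 0.05, and 0 were called by limma-voom over all peaks, 0 adjusted over the list alone and 0 by limma-trend. The median log2 fold change of these peaks was −0.02 and the mean 0.05. Sesn1, which encodes a stress-induced sestrin, held the peak of smallest p, 18448 bp from the gene, with a log2 fold change of 1.55 (SE 0.50).

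Cell cycle genes had 4 peaks called when adjusted over the list alone and 0 over all peaks by limma-voom or limma-trend. One of them, the gene-end peak of Mcm6, which encodes a subunit of the replicative helicase (chromosome 1, 128359463 to 128359963), had 445 ± 36.6 fragments (SD, n = 3) in WT and 260 ± 16.9 (SD, n = 4) in KO (log2 fold change −0.77, SE 0.16). The others, named after their values were seen, were a pair of E2f2 peaks with opposite log2 fold changes of 2.82 (SE 0.64) and −1.16 (SE 0.26) and a peak 36421 bp from Ccne1 with −0.72 (SE 0.16), and all 4 had an adjusted p of 0.0416 over the list. The list as a whole differed by 0.05 (camera adjusted p = 0.934). In the remaining lists no peak was called by limma-voom or limma-trend. The list difference was 0.06 for ductal and progenitor genes (camera adjusted p = 0.203), −0.06 for gastric-type metaplasia genes (0.585), −0.09 for epithelial-mesenchymal transition genes (0.239), −0.07 for Hippo-YAP targets (0.365), −0.07 for inflammation and acute-phase genes (0.341) and −0.13 for interferon response genes (0.0817). Of these, the interferon list was called lower without WT 2 (−0.17, adjusted p = 0.0245) and without KO 2 (−0.18, adjusted p = 0.0212). The epithelial-mesenchymal list was called lower without WT 3 (−0.28, adjusted p = 0.00207) and without KO 2 (−0.16, adjusted p = 0.0461), and the ductal list higher without WT 2 (0.11, adjusted p = 0.0386). These interferon, epithelial-mesenchymal and ductal calls used the preset correlation. With a correlation estimated over all libraries, each of these lists had a camera adjusted p of 0.874. With only 1 WT library kept, a setting without replicates of WT, differences went both ways. The epithelial-mesenchymal list differed by 0.26 with WT 3 and −0.44 with WT 1, and the gastric list by 0.15 with WT 3 and −0.24 with WT 2. With WT 1 the Hippo-YAP list differed by −0.31 and the ductal list by 0.27. In the order given, the peaks of smallest p of the 6 lists lay near Cd24a, Itga2, Mmp2, Birc3, Ptgs2 and Gbp2, with log2 fold changes of −1.33, −1.41, −1.78, −0.60, −0.79 and −1.25, all with an adjusted p of 0.876 over all peaks. At an unadjusted p under 0.05 these lists had, in the same order, 17, 7, 9, 10, 10 and 0 peaks higher and 5, 6, 11, 18, 12 and 5 lower in KO.

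Peaks at gene ends leaned lower in KO with the scaling used here. The strongest gene-end peaks of 14242 genes had a median log2 fold change of −0.20, which was −0.04 with cyclic loess and turned to 0.01 with quantile normalisation. Of 30265 gene-end peaks tested, 1863 had an unadjusted p under 0.05, 1450 of them lower and 413 higher, and 1 passed limma-voom after adjustment, that of LOC108167368, against 3 with limma-trend. Among gene-end peaks alone the interferon response list was lower in KO by 0.26 (camera adjusted p = 0.00164, and adjusted p = 0.783 with an estimated correlation). Its strongest gene-end peaks at Gbp2, Gbp3 and Ifit2, interferon-induced genes of which the last 2 were named after their values were seen, had log2 fold changes of −1.25 (SE 0.42), −0.63 (SE 0.24) and −0.79 (SE 0.30). At strongest gene-end peaks 2 of 23 interferon genes lay lower in every KO library, against a mean of 1.98 for random genes matched on mean count (one-sided permutation p = 0.609, adjusted p = 1). The acinar enzyme list was higher by 0.99 (camera adjusted p = 1.6e-30) and the acinar transcription factor list by 0.46 (2.8e-07), each with an adjusted p of 0.783 under an estimated correlation. The same held for the ductal list at 0.18 (0.0109) and the fibroblast list at −0.26 (0.0397).

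The peak sets of the libraries overlapped widely, and 61444 of the 161620 consensus peaks (38%) were covered by at least 1 bp of a peak in all 7 libraries. A single library's own peaks covered between 64.5% and 83.3% of the consensus. Peaks found in all WT and no KO library numbered 608, and those in all KO and no WT library 704. Of the 35 splits of the libraries, 6 gave at least as many for each kind, and the highest counts among the other splits were 1336 and 4181.

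The authors' deposited table held far more differences, nearly all lower in KO. Of the peaks in the authors' deposited table, 1471 had an adjusted p under 0.05, of which 1468 were lower and 3 higher in KO, with a median log2 fold change of −0.67 among the lower ones. Only 8081 peaks carry an adjusted p in the authors' deposited table, and the 4 peaks called by limma-voom on chromosome 12 are not among them. The smallest adjusted p at gene ends in the authors' deposited table belonged to Miip (1.9e-15, log2 fold change −2.21), Tmem267 (−1.99), Isoc2b (−1.83) and Hjurp (−1.31), chosen here after their values were seen. Of the p53 targets, Aen, Ccng1, Ei24, Fbxw7, Mdm2, Polk, Rap2b and Trp53inp1 held lower peaks in the authors' deposited table, 9 of the 32 list peaks with an adjusted p (28.1%, against 18.2% of all such peaks, Fisher's exact p = 0.165). The 8081 peaks are strong ones, with a deposited mean signal of at least 375.3 where the median of all peaks is 36.5. Gene-end peaks made up 83.4% of the 1468, against 78.5% of the 8081 and 20.4% of all tested peaks.

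In the refit with limma-voom 98.5% of these 1468 peaks were lower in KO, with a median log2 fold change of −0.32 (SD 0.15 across peaks). Of them 437 had an unadjusted p under 0.05 and 0 passed after adjustment over all 148420 tested peaks, by limma-voom. The authors' deposited table gives an adjusted p for 8081 peaks only, so the 0 and the 1468 come from unlike adjustments and cannot be set against each other directly. The shared direction of the 1468 peaks is no separate support, because they were picked as lower from the same libraries. Strong gene-end peaks leaned lower in general with this scaling. Of the strongest gene-end peaks of 14242 genes, 77.8% were lower in KO, with a median log2 fold change of −0.20. Across all peaks the fold changes of the authors' deposited table correlated with the refit at r = 0.328. Within the authors' deposited table the fold changes correlated with the difference of its own group means at r = 0.329, and 60% of peaks had the same sign in both.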

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

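The tests of chance, signal to noise, depth and copy number given here were chosen before their results were seen, and the borders of the chromosome 12 region and the tests of copy number at each peak were chosen after the calls were seen.

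Fragment ends outside all consensus peaks, used above only at Trp53 and along chromosome 12, differed between genotypes in 62 of 23828 bins of 100 kb (limma-voom, adjusted p under 0.05), 42 lower and 20 higher in KO. The bins lower in KO held Nlrp1b, which encodes an inflammasome sensor, on chromosome 11 (71200001 to 71300000, log2 fold change −3.59, adjusted p = 7.5e-06). They also held 4 neighbouring bins of the Defa genes, which encode alpha-defensins, on chromosome 8, with log2 fold changes of −5.13, −1.49, −2.40 and −3.17. Serpina1a and Serpina1c, for antitrypsin, lay in a bin of chromosome 12 with −1.47, and Serpina1b and Serpina1d in the next with −1.14. Bins higher in KO held Dynlt1b (1.10), the urinary protein genes Mup11 (1.58) and Mup19 (0.78), and Skint5 (0.79). Differences in DNA copy number or strain between the WT and KO mice were not tested at these genes, and the bins are not shown to follow from p53 loss. The Nlrp1b bin lies on the same chromosome as Trp53 (69580348 to 69591873). A strain difference inherited along with the floxed gene could not be told apart there from loss of p53. On chromosome 12 lay 33 of the 62 bins, 25 of them among the 98 bins between 16 and 26 Mb, all 25 lower in KO. In that region 83 of 464 tested peaks (17.9%) had an unadjusted p under 0.05, 52 lower and 31 higher in KO, and 15.3% differed at least 2-fold, against 5.12% elsewhere.

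The 4 called peaks and the 62 bins were weighed together. For a count of 4 peaks chance cannot be excluded, since 2 of the 35 splits of the libraries called at least 4. The other one called 3749, of which 0 were among the 4, and points to a structure of the libraries that runs across the genotypes. For the bins chance was argued against but not excluded, with 1 of 35 splits reaching 62 and 2 the highest of the others. A share of 1 in 35 is the smallest this design can give. The bins are not independent either, with 33 on chromosome 12 and 25 of these between 16 and 26 Mb. For signal to noise, the median log2 fold change of the called peaks kept 1.02 times its size with the share in peaks as a covariate, and 2 of the 4 stayed called. For depth, 4 of 4 kept their direction and an unadjusted limma-voom p under 0.05 after thinning to the shallowest library. Neither test can decide, because peaks picked for differences as large as 627 against 7 fragments could hardly lose them in this way. After thinning only the peak without a gene passed adjustment, and at LOC108167368 the log2 fold change went from −6.36 (SE 0.59) to −6.02 (SE 0.78), so the calls ended with the wider error and not with the fold. Without the pair of libraries of lowest share in peaks it was −6.05 (SE 0.72). The median log2 fold change outside peaks in the bins of the 4 peaks was −1.60, as a difference in DNA copy number or strain haplotype between the WT and KO mice predicts. The bins were unlike, with −2.62 at LOC115488029 and −2.66 at Gm46305, where such a difference may account for the called peaks. With −0.59 at LOC108167368 (limma-voom adjusted p = 0.0325) and −0.44 at the peak without a gene (adjusted p = 0.359), the bins there fell short of the 1 log2 unit it predicts. Such a difference stays undecided at these peaks, because a bin of 100 kb cannot show or exclude one that covers only part of it. An effect of p53 loss, or of age, on chromatin in this region stays open and untested, and the strain background of the mice is not given in the sources used here.

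Among the 4 KO libraries, 2 of 48 values examined had 1 library far from the other 3, and chance alone marks about 1 in 20. KO 4 had an endocrine list mean of 0.18, with the others from −0.18 to −0.12. KO 2 had a log2 accessibility of 1.83 at the distal Mmp2 peak, with the others from 0.23 to 0.34.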

How the results depend on the processing

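The settings that leave out the pair of libraries with the lowest share in peaks, keep 1 WT library, leave out chromosome 12 from 16 to 26 Mb, or count Trp53 outside peaks were chosen after seeing the data, as were the covariate and thinning for lists, the thinning before its own result was seen. The count of called peaks was 4, and 1 at gene ends. For peaks and gene ends in turn, it was 7 and 2 with quantile normalisation, 7 and 2 with cyclic loess, 9 and 3 with limma-trend, 24 and 5 with sample quality weights, 0 and 0 with a mean count of at least 30, 0 and 0 with fragments under 150 bp and 1 and 0 after thinning. The counts of 0 are from limma-voom, with 2249 and 5647 peaks at an unadjusted p under 0.05. With a mean count of at least 30, LOC108167368 kept a log2 fold change of −6.26 and Gm46305 one of −6.12. Their SE rose to 2.12 and 1.84, with unadjusted limma-voom p of 0.0151 and 0.00787. That of the peak without a gene was 9.4e-05, and LOC115488029 was not tested. At gene ends the count of called peaks was 2 with the trimmed mean of M values and 2 with both fragment ends counted. With the share in peaks as a covariate 2 peaks were called. The same 4 peaks were among those called under both normalisations, limma-trend and quality weights. Without the libraries of lowest share, and without the chromosome 12 region, 0 and 0 were called, with 4458 and 7650 peaks at an unadjusted p under 0.05. With only WT 1 kept, 14708 and 1579 were called, with only WT 2 78 and 30, and with only WT 3 1206 and 820, where the lone library is assumed to vary like the KO libraries. Leaving out each library gave 0 to 7 peaks and 0 to 3 gene-end peaks. The cause of these changes was not tested.

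Of 18 lists, 6 passed camera, 0 with an estimated correlation (the acinar enzyme difference of 0.84 then had an adjusted p of 0.874), and 4 to 8 when each library was left out. The acinar difference was −0.13 with only WT 3 kept and ranged from 0.52 to 1.33 with each library left out (adjusted p from 7.2e-36 to 1.0e-17). The difference of p53 targets was −0.031 at gene ends, −0.163 with only WT 3 kept, and −0.020 to 0.151 with each library left out. The fibroblast difference ranged from −0.616 without WT 3 to 0.071 without WT 1, where its direction turned, and was 0.519 with only WT 3 kept. The direction of the 6 lists was the same with quantile and cyclic loess scaling, and a single factor per library cannot change it.

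The Trp53 ratio of 0.80 was 0.52 outside peaks and 0.57 outside peaks relative to all fragments, and 0.72 to 0.87 with each library left out. With the upper 50% of each library's peaks by score, 179 peaks were in all WT and no KO library and 418 the reverse. Of the peaks in the authors' deposited table, 106 had an adjusted p under 0.01, and 40 were under 0.05 with a 2-fold change. Replicate numbers did not pair the libraries, since deviations of same-numbered libraries correlated at 0.28, 0.08 and −0.24. The replicate block called 7 peaks, 4 of them shared, and 1 at gene ends. Among named peaks 653 values kept their direction and side of the threshold, 38 lost and 11 gained a call, 19 changed sign without a call and 0 with one. Not run were motif content and GC corrections (no genome used here), a sex covariate (no X or Y in the files used), and DESeq2 or edgeR (the recounted fragments were fitted with limma alone). Restriction to autosomes changed nothing, since all fragments were autosomal.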

Other observations

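The tests of chance for the lists, of other cell types and of signal to noise for the acinar list, of the weight of WT 3, of signal to noise for the authors' peaks, of correlation between lists, and of the p53 target and strongest gene-end peaks were chosen only after the result was seen, and that of depth for the acinar list after the data but before its own result.

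At the strongest gene-end peak of each gene, p53 targets stood lower in KO, as genes in general did with median-of-ratios scaling (median −0.20) but not with quantile normalisation (0.01). Of 37 p53 target genes, 34 had a log2 fold change below 0 there, with a median of −0.23, and 8 lay lower in every KO library than in every WT library. These were Bbc3, Fas, Phlda3 and Pmaip1, which act in cell death, the p53 regulators Mdm2 and Trp53inp1, and Ckap2 and Polk. Log2 fold changes were −0.39 (SE 0.15) at Bbc3, −0.48 (SE 0.19) at Fas and −0.52 (SE 0.20) at Pmaip1. Random genes matched on mean count gave a mean of 5.38 such genes (95% of draws from 2 to 10) and a median log2 fold change of −0.23, and the one-sided permutation p was 0.152 (adjusted p = 1 over the 18 lists). Cell cycle genes had 8 of 32, Ccnb1, Ccne1, Cdk2, E2f1, Mcm4, Mcm5, Mcm6 and Pcna, against a matched mean of 4.44 (p = 0.0644 by the same permutation, adjusted p = 1). Acinar enzymes had 0 of 33, with a median log2 fold change of 1.11.

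The acinar enzyme list was higher in KO by 0.84, with WT 3 at the level of the KO libraries. The exact permutation p of this difference was 0.229. For the 6 of 18 lists called in all chance cannot be excluded, since 22 of the 35 splits of the libraries called at least 6, with 15 the highest of the others. The acinar difference kept 1.13 times its size with the share in peaks as a covariate and 1.05 times after thinning. Neither test can decide on signal to noise or depth. The mean share in peaks was 39.1% in WT and 36.0% in KO, so this covariate could remove little. Random thinning hardly moves a scaled list mean. Without the pair of libraries of lowest share in peaks, WT 2 and KO 4, the difference was 0.60 (camera adjusted p = 7.3e-15). It was 0.52 without WT 1, whose share was 40.9%. WT 1 and WT 2 had the lowest list means, so neither fall can be tied to the share in peaks, and signal to noise stays open. More cells of other types in WT cannot be told apart from a change within acinar cells, because the marker lists of immune cells (−0.13) and fibroblasts (−0.25) were lower in KO, while those of endothelial cells (0.06) and endocrine cells (0.01) were higher by at most 0.205 of their larger SD. The sort against CD45 would remove immune cells. The direction turned without WT 1 for the fibroblast list (0.07), without WT 3 or KO 2 for the endothelial list (−0.10 and −0.04) and without WT 1 or KO 4 for the endocrine list (−0.09 and −0.07). Across the 7 libraries the fibroblast list ran against the acinar enzyme list, with 0.35, −0.14 and −1.0 in WT 1, WT 2 and WT 3. Over 5 marker lists tested, exact permutation gave Pearson's r of −0.879 (p = 0.00337, adjusted p = 0.0169) and Spearman's rho of −0.964 (p = 0.00278, adjusted p = 0.0139) for fibroblasts, and r was −0.824 without WT 1 and WT 2. By the same permutations the immune list had r = −0.843 (p = 0.0125, adjusted p = 0.0312) and rho = −0.893 (p = 0.0123, adjusted p = 0.0205), and the erythroid list r = 0.834 (p = 0.0290, adjusted p = 0.0483) and rho = 0.929 (p = 0.00675, adjusted p = 0.0169). The endothelial list had r = −0.595 (p = 0.177, adjusted p = 0.221) and rho = −0.857 (p = 0.0238, adjusted p = 0.0298), and the endocrine list r = 0.509 (p = 0.252, adjusted p = 0.252) and rho = 0.75 (p = 0.0663, adjusted p = 0.0663). Without WT 1 and WT 2, in this order, r was −0.685, 0.782, −0.872 and 0.755. More fibroblasts in the libraries with less acinar signal therefore stay open, and how far the sort for CD49F removed such cells was not measured. The erythroid list, in contrast, ran with the enzymes. The acinar enzyme list ordered the 7 libraries as the first principal component did, from WT 1 lowest to KO 4 highest. Lists other than cell markers followed this axis too, and the epithelial-mesenchymal list fell from 0.28 in WT 1 to −0.44 in KO 4. No baseline of other lists was tested, so these correlations cannot tell the content of a cell type from this shared axis. A hypothesis left open is that acinar chromatin may close with age in the older WT mice, to a different extent in each mouse, which the design does not separate from p53 loss and which WT and KO mice of 1 age would test.

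The lower peaks of the authors' deposited table were mostly gene-end peaks, as were the strong peaks that carry an adjusted p there (83.4% against 78.5%), and in the refit WT 3 carried most of their difference. The median log2 difference from the KO mean was 0.70 for WT 3, against 0.13 for WT 1 and 0.16 for WT 2, so the larger of the others reached 0.232 of WT 3, as a large weight of WT 3 predicts. With the share in peaks as a covariate the median log2 fold change of these peaks kept 0.874 of its size. This can hardly decide on signal to noise, because the mean share differed little between genotypes (39.1% in WT and 36.0% in KO). Enrichment of fragment ends at gene ends was not used as a covariate. It was highest in WT 3, at 19.3, against 17.1 in WT 1, 14.9 in WT 2 and at most 15.8 in KO. Signal to noise at gene ends therefore stays open as a cause. After cyclic loess the median log2 fold change of these peaks was −0.06. This does not tell noise from a true loss, because that scaling centres strong peaks in either case. Over the strongest gene-end peaks, 1577 of 14242 (11.1%, where chance gives 2.86%) were lower in every KO library, and chance cannot be excluded, since 3 of the 35 splits separated as many and the highest of the others was 1787. A p53-dependent loss of promoter accessibility stays open, and the authors' design, which may weight the libraries differently, is not given in the sources used here.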
